A study of Homo sapiens with 6 samples.

How the data were processed

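The series holds 6 one-colour Affymetrix arrays of total RNA from MCF7 cells, 3 after transfection with a negative control RNA duplex and 3 after transfection with a miR-22 duplex. Per the labels' protocols, RNA was extracted with Trizol 24 h after transfection, biotin-labelled cRNA was made by the manufacturer's standard protocol, and the duplexes were given at a dose written "50nm", read here as 50 nM. The authors deposited linear intensity values, 1 signal per probe set and array, for 54675 probe sets including 62 array controls. The program that made these signals, its background correction and its scaling between arrays are not given in the sources used here, and no detection calls were used. Any scaling or background step that the authors applied sets the spread of dim probe sets and the size of their changes.

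The signals ran from under 1 to above 10000, and log2 was taken with no pseudocount. The array medians differed by at most 0.48 on the log2 scale, under the limit of 0.5 set for rescaling, so values were used as deposited, with quantile normalization and median centring as alternatives. Arrays had correlations across probe sets of 0.904 to 0.911 within groups and 0.901 to 0.907 between groups, and 1 probe set had identical values in a pair of arrays.

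Probe sets were named from the platform annotation given with the series: 41097 had 1 gene symbol, 1801 several, and 11721 others, apart from array controls, none. Symbols were updated through Entrez identifiers, which matched for 19735 of 19775 genes. A gene was represented by the probe set of highest mean among those with its symbol alone, and no gene was named from a probe set with several symbols. Array control probe sets that carry the symbol of ACTB or GAPDH were kept among the probe sets of these genes. Genes were tested if this mean reached the 40th percentile of all non-control probe sets, a log2 value of 3.58 or a signal of 11.9, which left 14272 genes. A group with a mean below this level is called dim. Where 1 group was dim, the fold is given as at least the brighter group's mean over this level; this is a level set from the data, not a measured background.

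Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05) without a replicate block. The 23 gene lists, with 507 entries, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, beside camera with the estimated correlation and fry. Lists of reported miR-22 targets and of pathway genes came from general knowledge of the field. ESR1 and MYCBP of the target list may have been chosen as targets by the study on these samples. A p adjusted over the list alone used the members tested. Array level and the 3' to 5' ratios of GAPDH and ACTB controls were compared by exact permutation.

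The genes named were chosen by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap; ESR1, MYCBP, MAX, PTEN, CDKN1A, HDAC4, CDK6, SIRT1, SP1, ERBB3, TET2, CDC25C and MIR22HG where measured; up to 4 members of smallest p from each list; and genes with an 8mer site for miR-22 in the 3' UTR. Genes named outside this rule were chosen after their values were seen: IFIT1, RIGI, IFIH1, CCL5, MX1 and TLR3 of the interferon list, LGALS9 of the target list, single immune cell markers, the lower genes listed for the fit without the intensity trend, and the families described last. The planned test of miR-22 seed sites in 3' UTRs was not run, nor were its alternatives, since no transcript or genome sequence was used here. No genome build is named for the values, so no coordinates are given.

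The steps were tested on simulated data drawn with the arrays' own means and spread for 14272 genes, with 200 genes changed, over 10 simulations of 3 arrays against 3. They recovered 0.4% of changes of 0.5 on the log2 scale, 44.0% of changes of 1, 82.2% of changes of 2 and 89.2% of changes of 3, with 9.13% false calls. In simulations where 1 list was shifted by -0.3 without correlation between genes, camera found it in 10 of 10 with the preset correlation, in 0 of 10 with the estimated correlation, and in 8 of 10 with the estimated correlation after median centring, and called 0 of 220 unchanged lists. The lists had a median estimated correlation of 0.40 in the deposited values. The simulations therefore do not show how often the preset correlation calls unchanged lists of correlated genes.

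Alternatives covered normalization, the filter on dim probe sets (none, and the 60th percentile), a pseudocount of 32, the probe set per gene, the spread model, the threshold, the set test, the replicate block and leaving out each array. Leaving out control array 2 and miR-22 array 3 together, which had the lowest medians, and median centring with the estimated correlation were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.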

Results

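Messenger RNA was measured in MCF7, an estrogen receptor-positive human breast cancer cell line, 24 h after transfection with 50 nM of either a negative control RNA duplex or a duplex of the microRNA miR-22. The purpose, by the title of the series, was to identify transcripts that respond to miR-22. Each group held 3 one-colour Affymetrix arrays, and their number limits the precision of every value below. The median probe set signal was 23.04, 18.5 and 24.7 in control replicates 1 to 3 and 24.0, 23.2 and 17.8 in miR-22 replicates 1 to 3. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Values are log2 probe set signals, changes are miR-22 minus control, and adjusted p-values come from limma unless another test is named.

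With the miR-22 duplex, the genes that rose most were those of the interferon response, the antiviral program that cells switch on after sensing foreign nucleic acid or interferon. IFIT3, which encodes an antiviral protein, rose from 4.94 ± 0.41 to 11.67 ± 0.19 (SD, n = 3), a 106.2-fold difference (log2 change 6.73, SE 0.17, adjusted p = 4.2e-25). XAF1 rose by 5.52, IFIT2 by 5.43, the mitochondrial nucleotide kinase gene CMPK2 by 5.18, the immunoproteasome subunit gene PSMB9 by 5.17, OAS2, whose product makes 2-5A and so activates RNase L, by 4.68, and IFI27 by 4.42. TRIM22, IFI44L and RTP4 completed the 10 largest rises. Their control means lay below the dim level of 3.58, so they were at least 9.04-fold, at least 11.3-fold and at least 5.97-fold higher, measured against that level, with adjusted p-values of 2.2e-06, 1.0e-06 and 7.4e-05. The control mean of PSMB9, 3.75 ± 1.21 (SD, n = 3), was barely above that level, so the size of its change is uncertain. Without moderation TRIM22 (adjusted p = 0.071), PSMB9 (0.16), RTP4 (0.16) and IFI44L (0.30) did not pass, nor did IFI44L without the intensity trend.

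Of the 25 tested members of the interferon list fixed beforehand, 23 rose and none fell. Adjusted over the list alone, 24 rose. Its mean change was 3.15 and its median 2.71. With the 3 members whose control group was dim set at their bound, the mean was 3.04 and the median 2.71. The list test passed (camera with a preset correlation, adjusted p = 5.9e-140), and with an estimated correlation it passed with adjusted p = 0.010. IFIT1 rose by 3.78, the RNA sensor genes RIGI and IFIH1 by 3.03 and 3.09, and the chemokine gene CCL5 by 2.70; these were picked from the list after their values were seen. The members that did not pass were MX1, dim in the controls, with a change of 1.94 (at least 2.93-fold) and adjusted p = 0.11, and TLR3, with a change of 0.45 and adjusted p = 0.89. Of the markers of immune cells, 0 of 11 tested members passed, and that list had a mean change of 0.00090 and a median of -0.17 (limma camera, adjusted p = 0.96).

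**Figure D1:**
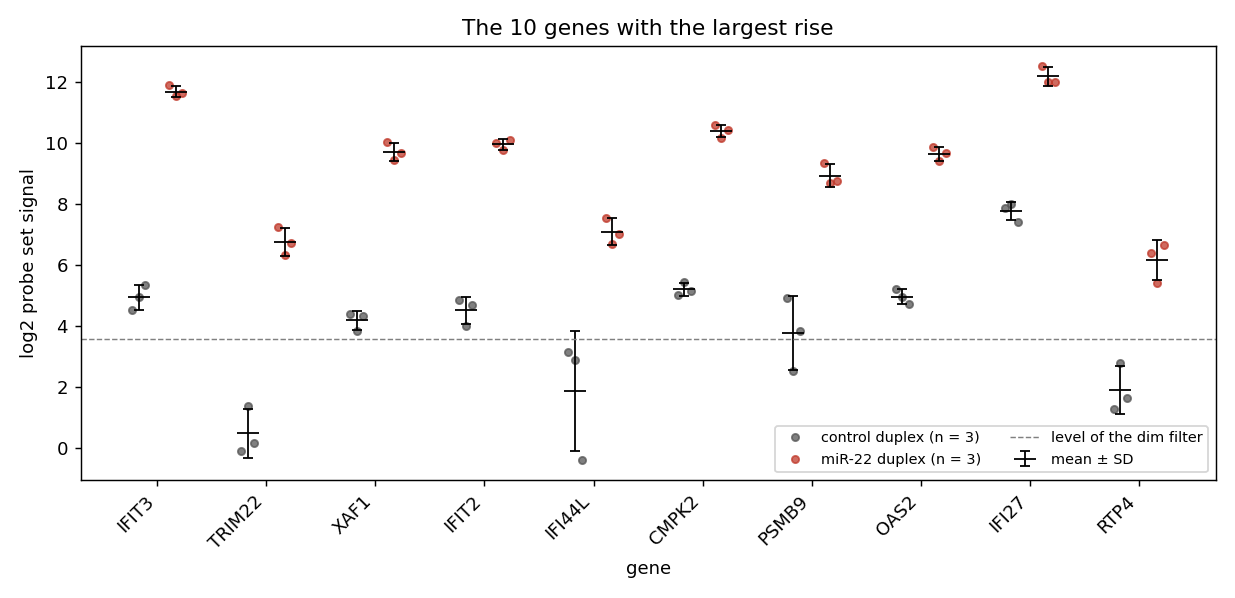
Log2 probe set signal (vertical axis) of the 10 genes with the largest rise (horizontal axis). Grey points are the 3 control arrays, red points the 3 miR-22 arrays, black marks the mean ± SD, and the dashed line the dim level of 3.58. For each gene all 3 miR-22 values lie above all 3 control values, and the control means of TRIM22, IFI44L and RTP4 lie under the line.

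Across all 14272 genes tested, 217 were higher and 217 lower in the miR-22 arrays at an adjusted p under 0.05, while 1704 passed at an unadjusted p under 0.05. The rises were the larger changes. The higher genes had a median change of 1.15 and the lower genes one of -0.67, and 122 rose but 19 fell by at least 2-fold. The groups did not overlap for 216 of the higher and 215 of the lower genes. They did not overlap for 15.9% of all tested genes, where chance gives 10%. The count of lower genes was the less stable: it was 5 against 78 higher genes without the intensity trend in the spread, 6 against 41 without moderation, 61 against 131 with the mean of all probe sets of a gene, and 532 against 456 after quantile normalization. It was 111 without control replicate 1, 118 without control replicate 3, 134 without miR-22 replicate 3, and 97 at an adjusted p under 0.01.

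ESR1, the gene of estrogen receptor alpha and a reported target of miR-22, fell from 10.95 ± 0.18 to 10.43 ± 0.14 (SD, n = 3), so that the control level was 1.43-fold the miR-22 level (change -0.52, SE 0.13, adjusted p = 0.018). Among the 31 tested genes of the list of reported miR-22 targets, ERBB3, a receptor of the epidermal growth factor receptor family, fell by 0.48 (adjusted p = 0.028) and WRNIP1, whose product interacts with the Werner helicase, by 0.51 (adjusted p = 0.033). The other 28 did not pass. ESR1 may have been reported as a target from these same samples, so its place in the list may not be independent of its fall here. Adjusted over the list alone, 6 members fell and 1 rose, LGALS9, with a change of 2.35 from a dim control level (at least 2.80-fold; adjusted p over all genes = 0.067). The list had a mean change of -0.19 and a median of -0.28 and passed the list test (limma camera, adjusted p = 0.0019), but not with an estimated correlation (adjusted p = 0.98). Of the other targets named beforehand, CDKN1A had a change of -0.41 (adjusted p = 0.11), SIRT1 -0.42 (0.27), TET2 -0.35 (0.39) and BMP7 -0.43 (0.066). CDC25C, with -0.17, MAX, with -0.03, HDAC4, with 0.02, CDK6, with 0.18, and SP1, with 0.08, did not pass either, at adjusted p-values of 0.82 or more. MYCBP, PTEN and MIR22HG were not analysed here, since no probe set carried their symbol alone. ESR1 did not pass without control replicate 1 (adjusted p = 0.17), control replicate 3 (0.063) or miR-22 replicate 3 (0.056), nor without the intensity trend (0.40), without moderation (0.35) or as the mean of all its probe sets (change -0.12, adjusted p = 0.98). That mean weighs its bright probe set equally with those near or below the dim level. ERBB3 lost its call in 8 and WRNIP1 in 10 of 18 other settings, and the target list did not pass without control replicate 3 (limma camera, adjusted p = 0.066).

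Genes that estrogen induces in breast cancer cells were lower in part. PGR, the progesterone receptor gene, fell by 1.10 (SE 0.22, adjusted p = 0.0021), MYB, a transcription factor gene, by 0.67 (SE 0.13, adjusted p = 0.0014), RAB31, which encodes a small GTPase, by 0.59 (adjusted p = 0.0083), and IGFBP4, which encodes a binding protein of insulin-like growth factors, by 0.70 (adjusted p = 0.040). These were 4 of 27 tested members, and none rose. Adjusted over the list alone, 7 fell and 1 rose. The list had a mean change of -0.22 and a median of -0.15 (limma camera, adjusted p = 0.0033; adjusted p = 0.98 with an estimated correlation). Among 17 genes that estrogen represses, BLNK, a B cell linker gene, rose by 1.15 (adjusted p = 0.0025). Adjusted over the list alone, 1 member rose, BLNK, and 1 fell, BMP7. TP53INP1, with -0.41, and KLF6, with 0.33, did not pass. That list did not pass (adjusted p = 0.95), and its mean of 0.01 and median of -0.04 differ in sign. IGFBP4 lost its call in 11 of 18 other settings, RAB31 in 4, among them without control replicate 1, PGR and MYB in 3 each and BLNK in 2.

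**Figure D2:**
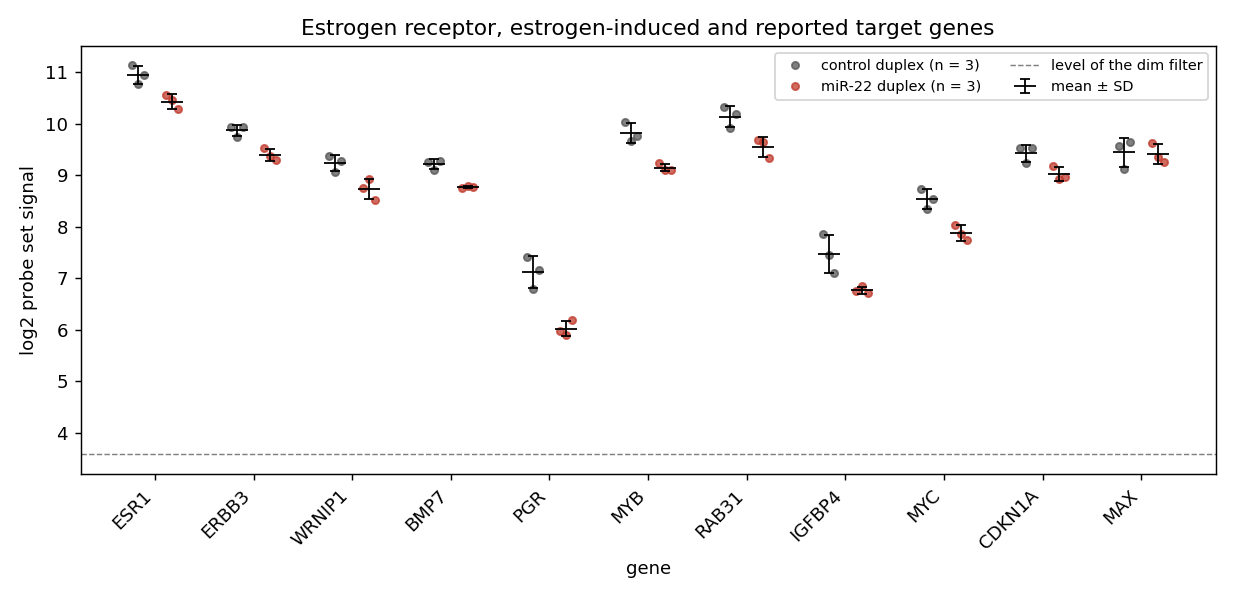
Log2 probe set signal (vertical axis) of the estrogen receptor gene and of target, estrogen-induced and MYC-related genes named by the rule fixed beforehand (horizontal axis). Grey points are the 3 control arrays, red points the 3 miR-22 arrays, black marks the mean ± SD, and the dashed line the dim level of 3.58. ESR1, ERBB3, WRNIP1, PGR, MYB, RAB31, IGFBP4 and MYC passed at an adjusted p under 0.05, while BMP7, CDKN1A and MAX did not.

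MYC, the transcription factor gene that drives growth programs, fell from 8.54 ± 0.19 to 7.88 ± 0.16 (SD, n = 3; change -0.66, SE 0.15, adjusted p = 0.0075). It was the 1 of 12 tested genes of the MYC network to pass. MYCBP2, with 0.59, MXI1, with -0.37, and MXD1, with -0.33, did not (list adjusted p = 0.79; over the list alone 1 rose and 2 fell). None of 25 tested genes that MYC activates passed, over all genes or over the list alone. The smallest p among them belonged to ODC1, the polyamine synthesis gene, with -0.41 and adjusted p = 0.070, before EIF4E with -0.27, PA2G4 with -0.26 and HSPE1 with 0.26 (limma camera for the list, adjusted p = 0.35). MYC lost its call without control replicate 1, without the intensity trend and without moderation.

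Among cell cycle genes, few passed. None of 25 tested G2/M genes passed over all genes, and 2 were lower over the list alone. The mitotic motor gene CENPE had a change of -0.51 (adjusted p = 0.069), TOP2A one of -0.42 (0.097), KIF20A one of -0.38 and BUB1B one of -0.39. The list had a mean of -0.15 and a median of -0.10 and passed with the preset correlation (limma camera, adjusted p = 0.022), but not with an estimated correlation (adjusted p = 0.98) or after median centring of the arrays (adjusted p = 0.055). In all, the G2/M list lost its call in 11 of 19 other settings. Of 24 tested G1/S and DNA replication genes, CHAF1A, a chromatin assembly factor gene, rose by 1.18 (adjusted p = 0.037), a call lost in 11 of 17 other settings, and MCM6, POLA1 and SLBP had changes of -0.30, -0.50 and -0.31 that did not pass (list adjusted p = 0.20; 1 rose over the list alone). Among 18 tested targets of p53, the stress cytokine gene GDF15 fell by 0.51 (adjusted p = 0.015) and SESN1, a sestrin gene, by 0.76 (adjusted p = 0.018), while TP53INP1 had a change of -0.41 (adjusted p = 0.18). That list did not pass (adjusted p = 0.14; 3 fell over the list alone), and GDF15 lost its call in 7 and SESN1 in 6 of 18 other settings.

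The 10 largest falls were smaller than the 10 largest rises. MYO7B, an unconventional myosin gene, and NEU4, a sialidase gene, were dim in the miR-22 arrays. Their control levels were at least 3.86-fold and at least 4.26-fold their miR-22 levels, measured against the dim level (adjusted p = 0.010 and 0.011). HEY2, a transcription factor gene of the Notch pathway, fell by 2.16 (SE 0.54), the homeobox gene NKX2-8 by 1.75, COL12A1, a collagen gene, by 1.74, NEIL2, a DNA glycosylase gene of base excision repair, by 1.53, and CASTOR2 by 1.31. SRF, the serum response factor gene, fell by 1.21 (SE 0.26, adjusted p = 0.0044), and SLC4A2, an anion exchanger gene, by 1.21. Of 2 SRF probe sets above the dim level only 1 went this way, and SRF did not pass with the mean of all its probe sets. HEY2 and SLC4A2 varied widely between the miR-22 arrays (SD 1.74 and 1.16, n = 3). DANCR, a long noncoding RNA, fell from 8.81 ± 0.14 to 7.61 ± 0.40 (SD, n = 3, change -1.20, SE 0.17, adjusted p = 5.9e-06). DANCR lost its call in 2 of 18 other settings, without the intensity trend and without moderation, and NEU4 and SRF in 3, against 5 to 10 for the other genes of this group.

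Other groups fixed beforehand held 1 or 2 changed genes each. In apoptosis, CASP8, an initiator caspase gene, rose by 0.86 (adjusted p = 0.00033) and MCL1, a survival gene of the BCL2 family, by 0.50 (adjusted p = 0.020), 2 of 21 tested members both over all genes and over the list alone, with XIAP at 0.35 and BIK at 0.41 not passing (list adjusted p = 0.20). In the microRNA machinery, DDX6, an RNA helicase gene of P-bodies, fell by 0.52 (adjusted p = 0.013), 1 of 18, with the mean of its probe sets going the other way (0.17, adjusted p = 0.90); CNOT1, AGO3 and TARBP2 had changes of -0.35, -0.66 and -0.34 (list adjusted p = 0.35). ESRP1, an epithelial splicing regulator gene, fell by 0.50 (adjusted p = 0.018), 1 of 20 epithelial genes, beside MUC1 at -0.34, CLDN3 at 0.24 and CDH1 at -0.20; the list did not pass (adjusted p = 0.95), and its mean of -0.01 opposes its median of 0.04. RPL14 fell by 0.50 (adjusted p = 0.029), 1 of 19 tested ribosomal protein genes, beside RPL3 at -0.16, RPS6 at -0.12 and RPS19 at 0.07 (list adjusted p = 0.89). ERBB3 was the 1 of 20 genes of PI3K and mTOR signalling to fall, with IRS2 at -0.42, IGF1R at -0.31 and MTOR at -0.87 not passing (list adjusted p = 0.38). ESRP1 and MCL1 lost their calls in 9, RPL14 in 10, DDX6 in 4 of 18 and CASP8 in 3 of 17 other settings. For DDX6, ESRP1, RPL14 and ERBB3 the count over each of these lists alone was also 1.

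In 9 further lists no member passed, over all genes or over the list alone, and no list passed. The unfolded protein response had a mean change of 0.04 over 18 genes (adjusted p = 0.81), with EDEM1 at -0.43, XBP1 at -0.28, DNAJB9 at 0.28 and DDIT3 at 0.48. Cholesterol synthesis had 0.13 over 14 genes (0.26), with INSIG1 at 0.31, NSDHL at -0.32, LSS at 0.26 and SQLE at -0.21. Folate and one-carbon metabolism had -0.20 over 14 genes (0.18), with MTHFD1 at -0.34, GART at -0.46, MTHFD2 at -0.28 and PSPH at 0.38. The hypoxia response had -0.08 over 18 genes (0.39), with ALDOC at -0.35, KDM3A at -0.30 and P4HA1 at -0.22. Chromatin acetylation had -0.06 over 22 genes (0.60), with NCOA1 at -0.53, SIRT7 at -0.35 and HDAC1 at -0.29. Oxidative phosphorylation had -0.06 over 24 genes (0.51), with ATP5PB at -0.29, UQCRC2 at -0.27, NDUFS1 at -0.26 and NDUFA9 at 0.27. Mesenchymal genes had 0.01 over 12 genes (0.96) with a median of -0.23, and among them were THY1 at 1.004, FN1 at -0.30, S100A4 at -0.45 and VIM at -0.23. Basal and myoepithelial genes had -0.11 over 9 genes (0.95), with CAV2 at -0.32, ACTA2 at 0.79 and ITGB4 at 0.27. ITGA6 was dim in the miR-22 arrays, and its control level was at least 2.74-fold its miR-22 level. Immune cell genes, the last of these lists, had TYROBP at -1.32, CD53 at -0.61 and MS4A1 at 0.80, and ITGAM, dim in the controls, at least 2.21-fold higher with miR-22. The list tests of this paragraph are limma's camera with the preset correlation.

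**Figure D3:**
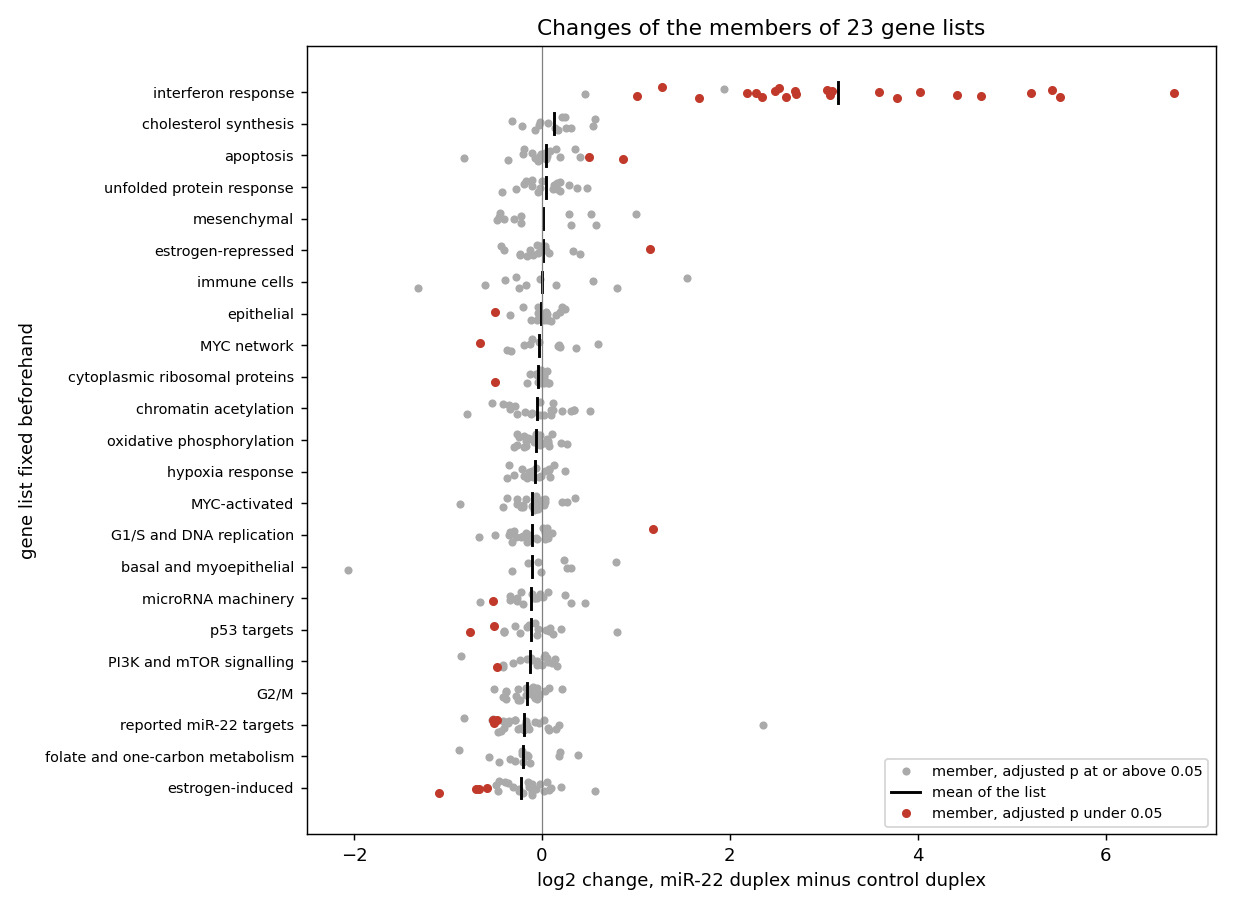
Log2 change, miR-22 minus control (horizontal axis), of each tested member of the 23 gene lists (vertical axis, sorted by mean). Red points have an adjusted p under 0.05, grey points do not, and the black bar is the mean of the list. The interferon response list, with a mean of 3.15, stands apart from the other lists, whose means lie between -0.22 and 0.13.

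No difference in RNA quality or array level passed an exact test. The log2 ratio of the 3' over the 5' control probe set was -0.22 ± 0.01 in the controls and -0.16 ± 0.05 with miR-22 for GAPDH (SD, n = 3, two-sided exact permutation p = 0.2), and 0.22 ± 0.07 and 0.23 ± 0.05 for ACTB (two-sided exact permutation p = 0.7). The median log2 signal was 4.45 ± 0.22 and 4.42 ± 0.24 (two-sided exact permutation p = 0.7). Adjusted over the 3 measures the p-values were 0.6, 0.7 and 0.7, and 3 arrays against 3 cannot give a p below 0.1.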

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

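The tests of explanations in this part were chosen after the results were seen, and the interpretations are hypotheses. Signal outside the compared genes also moved. The 4 array control probe sets whose identifier names ISGF3A, a component of the interferon-activated transcription complex ISGF3, read 1 transcript and were higher in all 3 miR-22 arrays than in all 3 control arrays. Their mean log2 differences, miR-22 minus control, were 1.74 for the 3' probe set, 2.52 for the 5' one, and 2.28 and 1.95 for those of the middle. The annotation used here gives them no gene symbol, and the gene table lists ISGF-3 as an older name of both STAT1, the member of the interferon list without a probe set of its own, and STAT2. Of 6378 bright enough probe sets that carry several gene symbols or none, 36 were higher and 27 lower with the miR-22 duplex (limma, adjusted p under 0.05 among 32768 probe sets). The largest rise among them was 3.29.

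The interferon response genes were higher in the miR-22 arrays, with a mean log2 change of 3.15 over 25 tested members. RNA of leukocytes in the miR-22 cultures would bring their abundant transcripts along. The 11 immune cell markers bright enough to test had a median change of -0.17 with a dim group set at the dim level, below the change of the interferon list. Its 95% bootstrap interval, -0.39 to 0.55, came from resampling the markers, not the arrays, so it leaves out the spread between arrays. The markers went both ways, from -1.32 for TYROBP to 0.80 for MS4A1 and 1.14 for ITGAM, and 0 of the 11 passed. ITGAM was dim in the controls, so its value is a bound, at least 2.21-fold higher with miR-22. Of the 5 untested ones, ITGB2 was dim in the controls too and at least 1.36-fold higher. LYZ, also dim in the controls, only reached the dim level with miR-22 (3.58), and CD3E, CD14 and CD3D were dim in both groups. Array scaling is argued against too, since the mean change of the list was at least 3.18 after quantile normalization or median centring. Among what stays open is whether the cells sensed the miR-22 duplex as foreign RNA, or whether the miR-22 sequence acted through its targets. With 1 duplex in each group, these cannot be told apart. Nor can they be told apart from a difference between cultures, since the labels do not say whether the replicates came from separate ones.

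ESR1 was lower in the miR-22 arrays on its one bright probe set. It has 9 probe sets, of which 5 lay above the dim level; 3 of these were lower and 2 higher, and 0 of the higher ones passed among all probe sets. The bright one had a change of -0.52 (adjusted p = 0.040 in limma among 32768 probe sets). The others of these 5 lay between 3.501 and 4.64 in the controls, too near the dim level to decide for or against a fall of the transcript. The fall therefore rests on the bright probe set alone. A fall through miR-22 sites in its 3' UTR was not tested.

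The small shifts of the reported target, estrogen-induced and G2/M lists passed with the preset correlation and were lost with the estimated correlation. If array scaling left in the deposited values made that correlation, it would vanish after median centring. For 1 of the 3 lists, G2/M, the estimated correlation after centring, 0.61, lay above the 95th percentile of 1000 random lists matched on expression, 0.57. For the target list it was 0.16 and for the estrogen-induced list 0.19, under the percentiles of 0.30 and 0.41. Random lists themselves had medians of 0.18 to 0.43, so scaling that depends on brightness may remain, and whether it explains the loss cannot be told apart from correlation between the genes.

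The 434 changed genes compare with at most 0 in the other 9 of the 10 splits of the 6 arrays into 3 and 3, and the 4 passing lists with at most 3. In each case 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05.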

How the results depend on the processing

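The alternatives were fixed before the data were examined, except those said to be added. The interferon list passed and kept its direction in every alternative run for it, with means of 3.05 to 3.29 when 1 array was left out. The number of higher and lower genes, 217 each or 50% higher, became 456 and 532 with quantile normalization and 275 and 204 (57.4% higher) with median centring. The median log2 change of all tested genes in the deposited values was -0.039. The numbers were 131 and 61 (68.2%) with the mean of all probe sets, 78 and 5 (94.0%) without the intensity trend, 41 and 6 (87.2%) without moderation, and 150 and 97 (60.7%) at an adjusted p under 0.01. The 5 lower genes without the trend were CLDN6, POLR3D, TNFRSF10C, ELOVL6 and GALC, of which the first 3 did not pass with it. Leaving out 1 array gave 154 to 240 higher genes, 111 to 258 lower genes, 40.7% to 67.4% higher, and 2 to 4 passing lists. Without control replicate 1, control replicate 3 and miR-22 replicate 3 the lower genes numbered 111, 118 and 134. The 4 passing lists became 1 with the estimated correlation, with fry, and with median centring plus the estimated correlation, an added alternative. The reported target list, with a mean shift of -0.19, and the estrogen-induced list, with -0.22, kept these means but not their calls with the estimated correlation (adjusted p = 0.98 for both) and fry (adjusted p = 0.73 for both), and had -0.16 and -0.19 after median centring with the estimated correlation (adjusted p = 0.98 for both). The G2/M list, with -0.15, lost its call with the stricter filter, the replicate block, the estimated correlation and fry at that same mean, after median centring with or without the estimated correlation (-0.12), and with plain probe sets first (-0.083). Over single arrays left out, the shifts ranged from -0.30 to -0.11 for the target list, which was lost without control replicate 3, from -0.31 to -0.14 for the estrogen-induced list, and from -0.22 to -0.10 for G2/M, which passed in 2 of 6. DDX6 turned from lower to higher with the mean of all probe sets (0.17, not passing). Of named genes, 118 values besides this one lost and 32 gained a call over the settings other than leaving out 1 array. In 1139 the call was unchanged, among them 17 of genes that did not pass in either setting and changed sign. The cause of these changes was not tested.

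The control and miR-22 arrays share the replicate numbers 1 to 3. With the replicate number as a block, 194 genes were higher and 170 lower, 354 of these 364 being among the 434, and 3 lists passed. Deviations of same-numbered arrays from their group means had correlations across genes of -0.01, -0.02 and -0.03, so the numbers do not show pairing. Without control array 2 and miR-22 array 3, an alternative added after the data were seen, 208 genes were higher and 231 lower, 328 of them among the 434. Fold changes of dim probe sets are limited by the signal over background, which was not given, and the 3' UTR site test and its alternatives were not run. camera and fry take no robust or unmoderated spread and no gene threshold, so the lists have no value under those settings.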

Other observations

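The gene families of this part were put together after the data were seen, so their counts describe these arrays and test no theme. Genes of MHC class I antigen presentation were higher with the miR-22 duplex in 14 of 15 tested members (limma, adjusted p under 0.05). TAP1 and TAP2, the peptide transporter genes, rose by 3.03 and 2.57 (SE 0.27 and 0.21), the immunoproteasome gene PSMB10 by 2.02, HLA-E by 1.11, HLA-B by 0.98 and B2M, the light chain gene, by 0.83 (SE 0.14). NLRC5, the activator gene of this set, was dim in the controls and at least 4.11-fold higher with miR-22. ERAP1, with a change of 0.72 and adjusted p = 0.17, was the member that did not pass. Of 6 tested interferon genes 2 passed, IFNL2, which rose by 3.35, and IFNL1, which rose by 2.71 (SE 0.32 and 0.29). The other 4 did not pass: IFNA17 had a change of 1.58, IFNA16 one of 0.65 and IFNA14 one of -0.36, and IFNE was dim with miR-22, its control level at least 1.27-fold its miR-22 level. IFNB1 was too dim for the test, with a mean of 1.43 ± 1.08 in the controls and 5.55 ± 0.27 with miR-22 (SD, n = 3), at least 3.94-fold higher with miR-22. Probe sets of HLA and interferon genes can also detect their close paralogs, so values of single members are uncertain.

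Of 8 tested metallothioneins, small metal-binding proteins whose probe sets can also detect each other's transcripts, 6 were higher, among them MT1H by 1.48 (SE 0.16), MT2A by 1.14 (SE 0.13) and MT1X by 1.06 (SE 0.14). ID4, ID3 and ID1, inhibitors of basic helix-loop-helix transcription factors, rose by 0.91, 0.80 and 0.50, while ID2 had a change of 0.30 that did not pass. Several genes of fatty acid synthesis and elongation were lower: ELOVL6 fell by 1.06 (SE 0.13, adjusted p = 1.0e-06), ELOVL2 by 1.05 (SE 0.16), ACLY, which supplies cytosolic acetyl-CoA, by 1.01 (SE 0.15), ELOVL5 by 0.52 and HACD2 by 0.46, 5 of 19 tested, whereas ELOVL7 rose by 0.59. FASN had a change of -0.37 with adjusted p = 0.19.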
